A study of Homo sapiens with 8 samples.

How the data were processed

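Chromatin immunoprecipitation followed by microarray hybridisation (ChIP-on-chip) was measured for histone H3 lysine 4 trimethylation (H3K4me3) and lysine 27 trimethylation (H3K27me3) in THP-1 cells, a human monocytic leukaemia line. Cells were untreated or held for 72 h in 50 ng/ml phorbol 12-myristate 13-acetate (PMA), per the labels. H3K4me3 had 3 control and 3 PMA arrays. H3K27me3 had 1 array per condition. The series' design text calls the H3K4me3 replicates biological.

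Each of the 8 arrays carried 2 colours. Per the labels, the immunoprecipitate was labelled with Cy5 (red) and input DNA of the same condition with Cy3 (green) on every array, so no dye swap was present and a dye effect cannot be separated from enrichment. The deposited scanner files hold spot intensities made with Agilent Feature Extraction 11.0.1.1, per the file headers, with probe positions on the human build hg19. The processed intensities were background-subtracted and dye-normalised by that software with a linear factor per channel, per the file headers. The deposited probe-level values of the authors are on a log2 scale, judged from their match to the scanner intensities. limma appears in the submitters' processing notes with no stated role or version, and the authors' normalisation is not given in the sources used here. Their medians per array lay between 0.04 and 0.08. They correlated across probes at r between 0.92 and 0.93 with the log2 ratio of the median red over the median green signal. The direction was therefore immunoprecipitate over input, while the normalisation stayed unknown.

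The values used were log2 of the processed red over the processed green signal. Spots flagged as non-uniform or population outliers were set to missing, and control spots (7666 per array) were left out. Each array was centred on its median over 171073 probes, with no loess or quantile step. The files assign every probe to a region, most of them 1800 bases wide, with a median of 7 probes per region. The value of a region on an array was the mean over its probes. The 122 regions with fewer than 3 probes were left out, which left 22996. The plan spoke of promoters. The files describe regions without naming their genes, so "array region" is used throughout.

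H3K4me3 in PMA against control was fitted per region with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Only the 6 H3K4me3 arrays entered. H3K27me3 had no replicates, so it has values and differences with the spread over probes, which is not a replicate error. A region counted as shifted at a difference of at least 1 log2 unit and as marked at a value of at least 1. Array precision is limited by the number of arrays. The share of probes well above background in the input channel was between 86.0% and 92.6% per array, and in the immunoprecipitate channel between 79.7% and 89.4%.

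The file headers place the arrays in 2 scan sessions of 4 arrays, each on its own slide. Session A held H3K4me3 control 1, H3K4me3 PMA 1 and both H3K27me3 arrays. Session B held H3K4me3 controls 2 and 3 and PMA 2 and 3. Session and slide are therefore the same split, and both sessions held both conditions. A fit with session as a block and values within each session are given beside the fit without it. In session A the H3K4me3 comparison had 1 array per side and no test. Replicate numbers also pair the arrays by the rule set in advance: deviations from the group means correlated at r = 0.91, 0.75 and 0.78 across regions for numbers 1, 2 and 3. That pairing came through the sessions, since within session B the difference between replicates 2 and 3 correlated at r = -0.06 between control and PMA.

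Named regions were chosen by a rule set before the data were examined. For H3K4me3 it took the 8 largest increases and 8 largest decreases among regions passing the threshold with all PMA arrays beyond all control arrays, and where too few passed, the smallest unadjusted p in each direction. For H3K27me3 it took the 8 largest differences each way among regions at 1 or more on either array with at least 80% of probes moving that way. A further set of H3K4me3 regions, called with session as a block, was chosen after the values were seen. It required a call under median centring, under quantile normalisation and over probes never flagged as outliers, the same direction in session A, and full separation in session B. These were ranked by the smaller difference over all probes or over never-flagged probes, a ranking adopted after a region of an earlier ranking was found to rest on flagged spots.

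The 25 gene lists fixed in advance, the panel of named genes and every gene set test were not run. The gene table at hand is on another build than hg19, and the files pair no region with a gene, so no region is named by gene and no coordinate was converted.

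The fits were tested on simulated data over 22996 regions, made with the session offsets and within-session noise of the H3K4me3 arrays. Of 100 regions changed by 1 log2 unit, the fit without a block recovered 0, with session as a block 92 and with a replicate block 85. Of 100 regions changed by 0.5, these counts were 0, 62 and 38, with 3 false calls under the session block. The simulation did not model a spread between cultures beyond that noise, nor a difference in range or input that goes with treatment. The recovered and false counts therefore hold for the simulated data only, and give no rate of false calls on the real arrays. The alternatives tried were loess, normexp (offset 50, on median signals because the files have no mean signal), the authors' values, quantile normalisation, the median over probes, the highest mean of 3 adjacent probes, a filter on dim probes, at least 5 probes, eBayes with trend and robust, both blocks, other thresholds, equal spread on both H3K27me3 arrays and each H3K4me3 array left out. Added after the data were seen were removal of each array's mean per probe length, restriction to probes never flagged, each session alone, the immunoprecipitate channel alone, and every H3K4me3 alternative again with session as a block. The count of regions whose PMA and control arrays do not overlap was also taken after that for every other split of the 6 arrays.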

Results

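H3K4me3, a mark of active and poised promoters, and H3K27me3, a mark laid down by Polycomb complexes, were profiled over 22996 array regions in THP-1 monocytic leukaemia cells. Control cells were compared with cells held for 72 h in 50 ng/ml PMA, a phorbol ester that activates protein kinase C and makes this line adherent and macrophage-like. H3K4me3 was measured on 3 control and 3 PMA arrays and H3K27me3 on 1 array per condition. All values are log2 of immunoprecipitate over input, centred on each array's median, and all coordinates are on hg19. Median immunoprecipitate signals ranged from 132 to 352 and median input signals from 145.5 to 213.5, in scanner units, over local backgrounds of 14 to 23.

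H3K4me3 arrays differed more between scan sessions than between treatments. H3K4me3 arrays of one session correlated across regions at r between 0.96 and 0.99, whereas H3K4me3 arrays of different sessions correlated at r between 0.79 and 0.82. H3K4me3 arrays of session B correlated more highly with the H3K27me3 arrays, which were scanned in session A, at r between 0.84 and 0.90. The H3K4me3 and H3K27me3 arrays of session A correlated at r between 0.80 and 0.83, so session did not set the grouping across marks. Regions are not independent replicates, so these correlations carry no test. Between H3K4me3 controls 1 and 2, of different sessions, 7972 regions differed by at least 0.5, against 56 between controls 2 and 3 of session B.

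**Figure D1:**
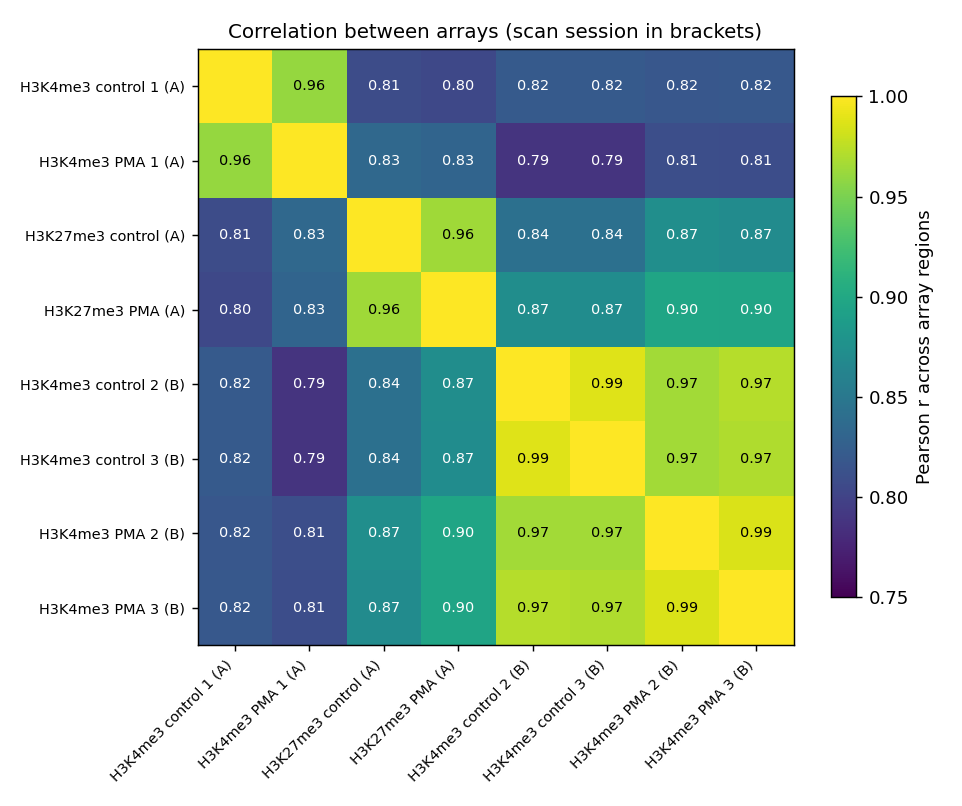
Pearson correlation across 22996 array regions between the 8 arrays, with the scan session (A or B) in brackets. H3K4me3 arrays of different sessions correlate at 0.79 to 0.82, below the 0.84 to 0.90 between H3K4me3 arrays of session B and the H3K27me3 arrays.

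The first comparison asked which regions differed in H3K4me3 between PMA-treated and control cells. At the region on chromosome 12 from 66220254 to 66222054, H3K4me3 was -0.70 ± 0.12 (SD, n = 3) in control and 0.56 ± 0.52 (SD, n = 3) in PMA, a 2.38-fold difference. This log2 difference of 1.25 was 0.73 with normexp, 0.79 without dim probes and 1.69 with the median over probes. At chromosome 17 from 7786822 to 7788622 H3K4me3 was 0.55 ± 0.05 (SD, n = 3) in control and -0.40 ± 0.24 (SD, n = 3) in PMA, 1.93-fold lower. This region has 3 probes, so it dropped out without dim probes and with at least 5 probes required. Its PMA minus control difference was -0.35 in the immunoprecipitate channel and 0.66 in the input. At chromosome 19 from 9694709 to 9696509 the values were 0.60 ± 0.07 and -0.06 ± 0.03 (SD, n = 3 each). Neither these nor any other region passed the test without a block. limma called 0 of 22996 regions at an adjusted p under 0.05, and 626 had an unadjusted p under 0.05. The 3 PMA arrays lay beyond the 3 control arrays in 8.85% of regions. Chance gives 10% for exchangeable arrays, which these were not: the other splits with 1 array of session A on each side gave 1.29% to 2.87%.

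None of the 16 regions named by the rule set in advance passed, and each carried an adjusted p of 1.00 from limma without a block. Their 8 higher members differed by 0.58 to 1.25 log2 units and their 8 lower members by -0.50 to -0.95. Among the lower ones, chromosome 1 from 35658243 to 35660043 went from -0.68 to -0.01 without dim probes. It was -0.22 with normexp and -0.25 with the authors' values. Chromosome 1 from 150692864 to 150694664 moved the other way without dim probes, from -0.65 to -0.95. In the fit with session as a block all 16 passed, with adjusted p of at most 0.0030. They were picked by their unadjusted p on the same arrays, so this pass lends no further support. Among the higher ones, chromosome 10 from 112256324 to 112258124 went from 0.65 ± 0.16 to 1.28 ± 0.07 (SD, n = 3 each). Chromosome 9 from 134584729 to 134586529 went from -0.28 ± 0.05 to 0.31 ± 0.10, and chromosome 1 from 26698766 to 26700566 from -0.25 ± 0.08 to 0.36 ± 0.10. At this chromosome 1 region PMA minus control was 0.05 in the immunoprecipitate channel and -0.50 in the input. At the chromosome 10 region these were 0.50 and -0.07. With the highest mean of 3 adjacent probes the chromosome 1 difference was 0.26. Among the 8 higher regions, only this chromosome 10 region and chromosome 12 near 66220254 differed more in the immunoprecipitate channel than in the input. All 8 lower regions differed more in the input. Among the lower ones, chromosome 15 from 48622320 to 48624864 went from 1.13 ± 0.02 to 0.50 ± 0.16. Chromosome 17 from 49336596 to 49338727 went from 0.88 ± 0.02 to 0.37 ± 0.03, and chromosome X from 51635397 to 51637197 from 0.67 ± 0.10 to 0.09 ± 0.07. The chromosome 17 difference of -0.50 was -0.26 with the median over probes, -0.28 with the authors' values and -0.29 with normexp. It was -0.60 without dim probes.

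With session as a block, limma called 3693 regions, 2744 higher and 949 lower in PMA. The error of this fit rests largely on replicates 2 and 3 of session B, which shared a slide. Between controls 2 and 3 the difference correlated at r = 0.002 across adjacent probes, against 0.19 for PMA minus control in session B. The SE and adjusted p of this fit may therefore hold little of the spread between cultures or preparations. A replicate block called 2806, of which 2132 were higher. Leaving out 1 array under the session block gave 1237 without PMA 2, 1350 without control 2, 1547 without control 3, 1739 without PMA 3, and 4212 without control 1 or PMA 1. Leaving out control 1 or PMA 1 is the same fit as session B alone, since the block absorbs the remaining array of session A. The balance between higher and lower depended on the scaling: after quantile normalisation the session block called 1730 regions, 769 higher and 961 lower, and the authors' values gave 2134, 903 higher and 1231 lower. Session B alone (2 arrays against 2) called 4212 regions, 3163 higher and 1049 lower, and after quantile normalisation 1910, 907 higher and 1003 lower. Of the 4212, 84.3% had the same sign in session A, where the single pair allows no test, against 65.6% of all regions. The differences in both sessions correlated across regions at r = 0.47 (rho = 0.46). After quantile normalisation r was 0.38, and 82.1% of the 1910 calls kept their sign in session A, against 62.3% of all regions. The median-centred difference correlated with the H3K4me3 level (r = -0.46) and with mean probe length (r = 0.46), so scaling may carry part of this agreement.

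**Figure D2:**
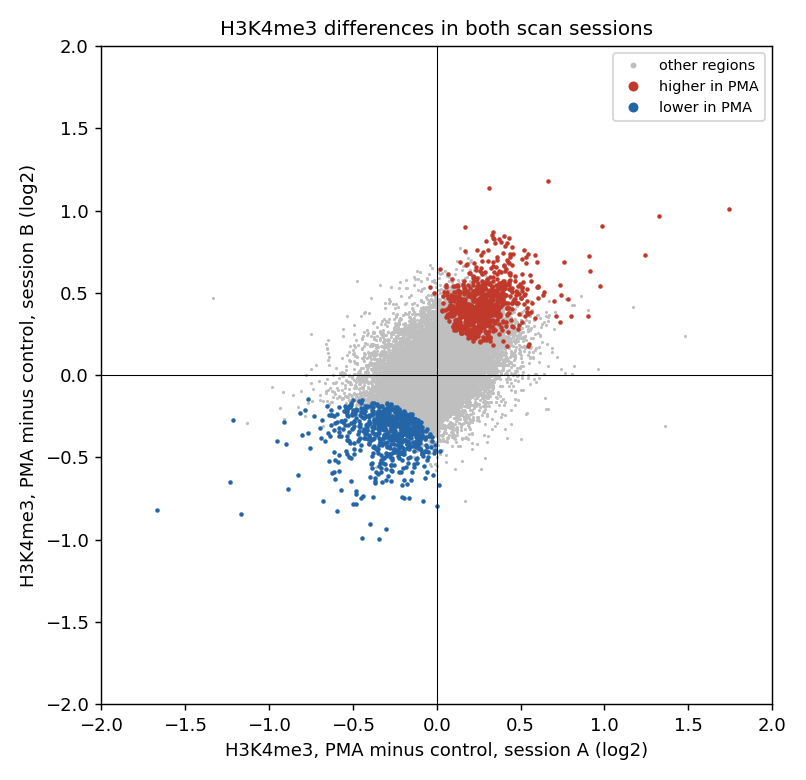
H3K4me3 difference of each array region, PMA minus control, in session A (1 pair, x axis) and session B (mean of 2 minus mean of 2, y axis), both in log2 units. Coloured points are the 733 higher and 688 lower regions called with session as a block under both median centring and quantile normalisation; they were called from the same arrays, so their place in the upper right and lower left is partly built in.

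Under both scalings the session block called 1421 regions in the same direction, 733 higher and 688 lower in PMA. The higher ones had a median control value of -0.40 and the lower ones of 0.25. Regions given next were chosen after their values were seen. Higher in PMA besides the region on chromosome 12 near 66220254 was chromosome 12 from 92534989 to 92537747, by 1.09 ± 0.08 (SE of the blocked fit; adjusted p = 0.00051), with differences of 1.33 in session A and 0.96 in session B. Chromosome 1 from 179111724 to 179113524 was higher by 0.93 ± 0.09 (SE) and chromosome 1 from 150546528 to 150548328 by 0.90 ± 0.10 (SE). Chromosome 2 from 238418273 to 238419631 was higher by 0.86 ± 0.14, chromosome 21 from 30516579 to 30518379 by 0.78 ± 0.08, chromosome 6 from 138188870 to 138190670 by 0.73 ± 0.08 and chromosome 14 from 95599340 to 95601140 by 0.71 ± 0.06. Lower in PMA was chromosome 3 from 167370789 to 167372589, by -1.10 ± 0.13 (SE; adjusted p = 0.0020), with -1.67 in session A and -0.82 in session B. Chromosome 15 from 50405013 to 50406813 differed by -0.84 ± 0.10, chromosome 9 from 136150130 to 136151930 by -0.81 ± 0.11, chromosome 19 from 31839690 to 31841490 by -0.78 ± 0.11, and chromosome 6 from 31125002 to 31127315 by -0.76 ± 0.08. Chromosome 8 from 103424417 to 103426217 differed by -0.75 ± 0.08 and chromosome 9 from 140498795 to 140500595 by -0.74 ± 0.10. Each of the 16 had an adjusted p of at most 0.0044 in the blocked fit. In the immunoprecipitate channel alone 14 of the 16 did not pass, of which chromosome 12 near 66220254 (1.31) and chromosome 15 near 50405013 (-0.97) kept their size. With the median over probes 6 did not pass, of which chromosome 2 near 238418273 (1.05), chromosome 17 near 7786822 (-0.82) and chromosome 8 near 103424417 (-0.75) changed little or were larger. Chromosome 14 near 95599340 fell to 0.24 with the median. With the highest mean of 3 adjacent probes, chromosome 6 near 138188870 fell to 0.27.

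**Figure D3:**
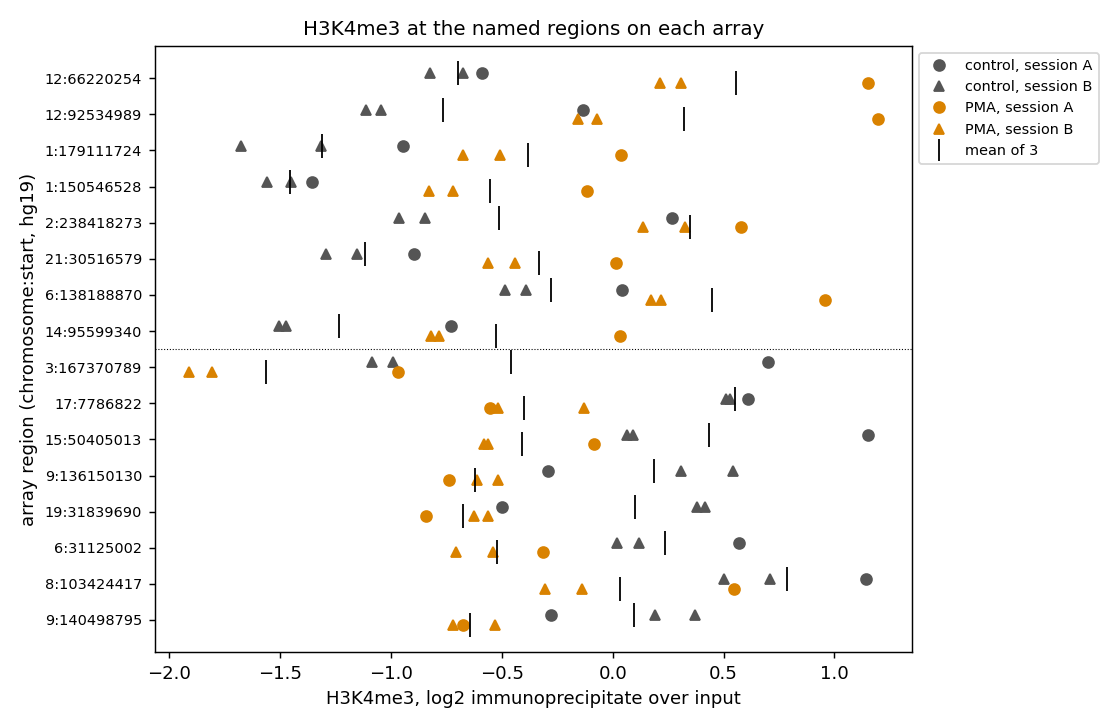
H3K4me3 (log2 immunoprecipitate over input, x axis) at the 16 regions called with session as a block, each point 1 array, with vertical ticks at the mean of 3 arrays; 8 regions above the dotted line were higher and 8 below it lower in PMA. At chromosome 12 near 92534989 the session A control array (-0.13) reaches the session B PMA arrays, while within each session PMA is higher.

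The input channel carried much of these differences. Over the 3693 blocked calls, a median of 57.8% of the difference came from the input, and the immunoprecipitate channel alone with session as a block called 25 regions, against 770 for the input channel alone. At chromosome 12 near 66220254 the immunoprecipitate part was 1.31 and the input part 0.11. At chromosome 21 near 30516579 these parts were -0.01 and -0.73, so its whole difference lay in the input. PMA arrays sat at lower slide positions than control arrays of the same mark in both sessions, so position and treatment cannot be told apart. The summary of the probes also mattered, as the median over probes gave 187 blocked calls.

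After adjustment only chromosome 19 departed from its expected number of higher calls, and no chromosome for lower calls. This does not show an even spread elsewhere. Without passing, chromosome 22 held 8 higher calls where 17 were expected, and chromosome 12 held 52 where 37.1 were. Chromosome 19 held 26 of the 733 higher regions where 47.2 were expected by its number of regions (Fisher's exact test, two-sided, odds ratio 0.53, adjusted p = 0.035 over both directions and all chromosomes). That test takes regions as independent, while H3K4me3 differences of neighbouring regions under 10 kb apart correlated at r = 0.16 in session A and 0.18 in session B, so this p is too small by an unknown amount. The 5749 regions with the lowest H3K4me3 held 1888 of the higher calls under median centring and 240 after quantile normalisation.

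The second comparison concerned H3K27me3, with 1 array per condition and hence no test. Of the 22996 regions, 4 were higher and 2 lower in PMA by at least 1 log2 unit. This count depended on the processing: it was 0 with the authors' values, 1 with normexp, 40 (30 higher, 10 lower) with the median over probes and 37 (16 higher, 21 lower) with the highest mean of 3 adjacent probes. The higher ones were chromosome 1 from 567704 to 569093 (-5.51 to -4.12, where the input stood at 207-fold its median), chromosome 1 from 54410698 to 54412588 (-0.36 to 0.69), chromosome 7 from 76089671 to 76091471 (0.84 to 1.84) and chromosome 8 from 66753469 to 66755269 (-0.08 to 1.00). The lower ones were chromosome 12 from 51156488 to 51158288 (1.02 to -0.06) and chromosome 19 from 6389648 to 6391014 (0.79 to -0.25). Over probes flagged on neither array, the difference at chromosome 1 near 54410698 was 0.35 and at chromosome 19 near 6389648 it was -0.40, which leaves 4 of the 6. The spread over probes was 1.08 at the chromosome 7 region and 1.11 at the chromosome 12 region, about the size of the differences themselves. At the chromosome 8 region it was 2.26, above the difference of 1.08, and 62.5% of probes moved that way. As a yardstick, H3K4me3 controls 2 and 3 differed by at least 1 in 1 region and by at least 0.5 in 56, PMA 2 and 3 by at least 0.5 in 49, and both H3K27me3 arrays by at least 0.5 in 101. Each of these pairs shared a slide. Across sessions, H3K4me3 controls 1 and 2 differed by at least 0.5 in 7972 regions and PMA 1 and 2 in 6576. The yardstick is of another mark, so it gives no replicate spread for H3K27me3.

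Among regions carrying H3K27me3 at 1 or more on either array, the differences were between 0.33 and 1.00 for the 8 largest increases and between -0.42 and -1.08 for the 8 largest decreases. Chromosome X from 51635397 to 51637197 went from 0.32 to 1.06 in H3K27me3, the region whose H3K4me3 was 0.67 in control and 0.09 in PMA. Its H3K27me3 difference of 0.74 was below the spread over probes of 0.94, and its H3K4me3 difference had an immunoprecipitate part of -0.07 and an input part of 0.58. Chromosome 18 from 44336539 to 44338339 went from 0.81 to 1.43, a difference of 0.63, or 0.43 over never-flagged probes, and chromosome 16 from 3067688 to 3070812 from 0.45 to 1.04. Chromosome 4 from 75309552 to 75311352 went from 1.68 to 1.20 and chromosome 16 from 10478611 to 10480411 from 1.27 to 0.66.

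The third comparison set both marks side by side. In control cells 373 regions reached 1 in both marks, 356 in H3K4me3 only and 232 in H3K27me3 only, and 22035 in neither. In PMA the counts were 349, 296, 168 and 22183. Independent marks would have overlapped in 19.2 regions in control and 14.5 in PMA. The values of both marks were correlated over all regions, as given below, so an overlap above these numbers follows from that. It does not tell regions that hold both marks from other sources of the correlation. Of the 373 regions with both marks in control, 276 had both in PMA, 53 had H3K4me3 only, 31 had H3K27me3 only and 13 neither. Of the 232 with H3K27me3 only, 38 had both in PMA and 111 neither. These are crossings of the threshold by regions picked for reaching it in control, so some return below it is built in. The mean H3K27me3 difference was -0.13 over those 232 regions and -0.06 over the 373. A threshold of 0.5 gave 3039 regions with both marks in each condition, and one of 1.5 gave 20 and 11. The count was 46 in control and 33 in PMA with normexp, and 5694 and 5426 with the highest mean of 3 adjacent probes. It was higher in PMA with the authors' values (109 and 118) and for the top 20% of each mark (3288 and 3463). Values of both marks correlated across regions at r = 0.87 (rho = 0.84) in control and r = 0.92 (rho = 0.90) in PMA.

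**Figure D4:**
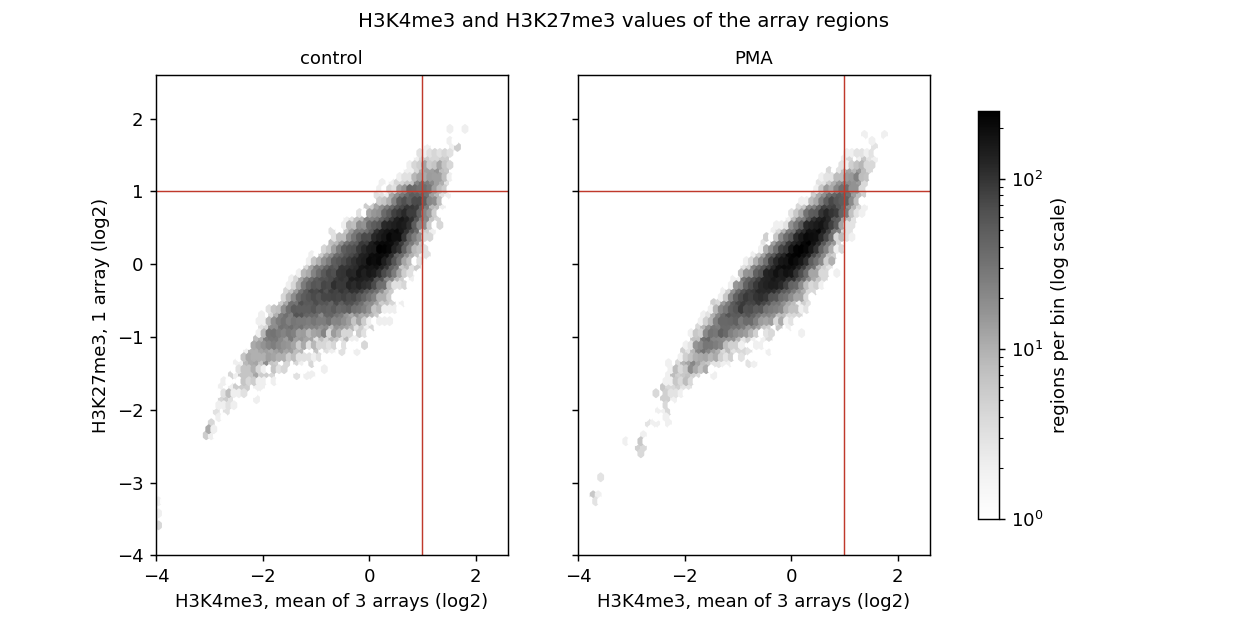
H3K4me3 (mean of 3 arrays, x axis) against H3K27me3 (1 array, y axis) for the array regions in control (left) and PMA (right), in log2 units, with regions below -4 outside the axes and red lines at the threshold of 1. The upper right corner holds the 373 regions with both marks in control and the 349 in PMA.

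The differences of both marks were weakly related, with a sign that depended on the arrays used. Across regions, the H3K27me3 difference and the H3K4me3 difference correlated at r = -0.07 (rho = -0.08). With the H3K4me3 difference of session A alone r was 0.0324, and with that of session B alone -0.11. The sign also turned without H3K4me3 control 2 (0.02), without control 3 (0.00824) or without PMA 1 (0.0407). With normexp r was -0.21 and with the authors' values -0.16. Among the 733 regions called higher in H3K4me3, 318 were lower in H3K27me3. Among the 688 called lower, 500 were higher in H3K27me3, with a median H3K27me3 difference of 0.09. That median was 0.02 among the 733 and 0.0004 over all regions. Of regions called lower in session B, 36.8% had a higher input on the H3K27me3 PMA array than on the control array. Over all regions lower in session B it was 42.6%. The input may thus carry part of this H3K27me3 difference, which 1 array per condition cannot test.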

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

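The tests by probe length, by correlation within the immunoprecipitate channel, by quantile normalisation, by slide position, by splits of the arrays, by lower calls on the other arrays and by the contrast between the marks were chosen after the result was seen.

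H3K4me3 arrays of session B resembled the H3K27me3 arrays more closely than they resembled the H3K4me3 arrays of session A. The input is not the whole source. In the immunoprecipitate channel the lowest correlation across marks still lay 0.0161 above the highest across sessions within H3K4me3. Input signals showed the same order in their medians, with overlapping ranges. Inputs of session B H3K4me3 arrays correlated with those of the H3K27me3 arrays at a median of 0.9237 (0.8987 to 0.9533). Between H3K4me3 arrays of different sessions the input median was 0.8998 (0.8818 to 0.9279). The resemblance was thus not confined to the immunoprecipitated DNA, and the input may carry part of it. Probe length, a stand-in for base composition, accounts for part: without it the median across marks lay 0.0234 above the highest across sessions, against 0.0516 with it. The lowest lay 0.00305 above, against 0.0215. It is thus argued against as the whole source by a narrow margin. H3K27me3 immunoprecipitates under those labels stay open. At 459 regions picked on the PMA arrays of session A for H3K4me3 over H3K27me3, the control arrays of session B exceeded the level predicted from H3K27me3 by 38.9% of the excess of control 1, above the bound of 10 percent set beforehand. That bound was ill chosen, since regions low in 1 preparation of H3K27me3 need not be low in another, and controls 2 and 3 had mean values of -0.17 there against 0.90 in control 1. A weaker enrichment in session B and differences between cultures stay open too, both untested.

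Regions called with session as a block were mostly higher in PMA. A narrower range of ratios on the PMA arrays is a candidate explanation for that imbalance. The SD over regions was 0.65, 0.85 and 0.84 on controls 1, 2 and 3, and 0.56, 0.76 and 0.78 on PMA 1, 2 and 3. After quantile normalisation 44.5% of the calls were higher. That step gives all 6 arrays the same distribution, so it draws the share towards balance whatever its source. The share therefore cannot tell a narrower range from a true gain in PMA. On the called regions 84.97% kept their direction in the immunoprecipitate channel. This met the bound of 80 percent set beforehand against the input as the source. That bound was ill chosen, since regions picked on the ratio lean that way in either channel (93.5% in the input), so the share decides nothing. Of the regions called in session B alone, 78.2% had that direction in the immunoprecipitate channel of session A, above the bound of 65 percent set beforehand. That bound was ill chosen too, since all regions higher in session B, called or not, already gave 68.7%. Higher calls gave 81.8%, and lower calls 67.2% against 54.7% of all lower regions. After quantile normalisation higher calls gave 76.4% against 66.4% of all higher regions, and lower calls 61.3% against 47.3%. The calls thus exceeded all regions of their direction under both scalings, while the input as the source stays open in both directions. In 3 of 3 sets of arrays PMA sat at lower slide positions, so position cannot be told apart from PMA treatment, the biological explanation.

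The 6 H3K4me3 arrays allow 10 splits, too few for a share under 0.05. With session as a block the real split gave 3693 calls and the highest of the others 0, so 1 of 10 gave as many. Without a block all 10 gave 0, the highest other included. A split that set arrays of session A with 1 of session B had 7782 regions at an unadjusted p under 0.05, against 626 for the real one, which points to the session structure. Of the splits that part all 3 pairs, the others had 4, 7 and 38 such regions.

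H3K27me3 values followed H3K4me3 values across regions. On the control arrays of session A they correlated at r = 0.81. Probe length is not the whole source, since r was 0.787 after its removal. Input brightness is not either, with a partial r of 0.758 at fixed input. H3K4me3 immunoprecipitates under the H3K27me3 labels stay open. The difference between the marks correlated at 0.786 across regions between control and PMA arrays, but so did that between H3K4me3 replicates 2 and 1 of different sessions, at 0.887, so the test does not tell marks from preparations. No biological explanation was tested, and enrichment that both antibodies share stays open as a possible explanation.

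At 2 regions every H3K4me3 pair was lower in PMA by at least 0.25 while the H3K27me3 array was higher by at least 0.75, a difference between marks that was not tested. The bound of 0.75 was chosen after the values were seen, and at 0.5 there were 11 such regions, with 1 the other way round. Chromosome 7 from 76089671 to 76091471 had an H3K27me3 difference of 1.00 and H3K4me3 pair differences of -0.38, -0.78 and -0.70. Chromosome 19 from 31839690 to 31841490 had 0.824 in H3K27me3 and -0.34, -0.98 and -1.01 in H3K4me3. The H3K27me3 spread over probes, 1.08 over 3 probes and 0.91, exceeded both differences. Most of the H3K4me3 difference lay in the input, with immunoprecipitate parts of -0.19 and -0.27 and input parts of 0.48 and 0.57. The 3 regions with the lowest H3K4me3 were examined for the brightness of their input, which stood far above the median. It was 207-fold the median at chromosome 1 from 567704 to 569093. At chromosome 5 from 79946354 to 79948154 it was 98.5-fold, and at chromosome 11 from 10529816 to 10532023 63.1-fold. Bright input was not confined to these 3, as chromosome X from 49177215 to 49179015 stood at 18.7-fold. H3K4me3 of the 3 regions in control was -5.85 ± 0.13, -5.28 ± 0.17 and -5.19 ± 0.22 (SD, n = 3). They were picked for these low values. H3K27me3 in control was low there too, at -5.51, -4.44 and -4.39. The input is the denominator of every ratio, so an input that bright lowers these values by itself. They need not be a level of the mark.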

How the results depend on the processing

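The H3K4me3 comparison without a block called 0 regions under 18 of 21 alternatives, with 189 to 2615 at an unadjusted p under 0.05. The exceptions were the replicate block (2806), the session block (3693) and session B alone (4212). The cause of other moves was not tested. Settings combined with the session block, the probe length removal, the restriction to unflagged probes, the single sessions and the single channel were chosen after seeing the data. With session as a block the count was 2134 with the authors' values, 187 with the median over probes, 350 with the highest mean of 3 adjacent probes, 1730 after quantile normalisation, 1762 (927 higher) after removing probe length means and 25 in the immunoprecipitate channel alone. Leaving out 1 array gave 1237 to 4212: 1350 without control 2, 1547 without control 3, 1237 without PMA 2 and 1739 without PMA 3. The 4212, without control 1 or PMA 1, is the same fit as session B alone. The share of higher calls was 74.3% under median centring, 66.6% with loess, 43.2% with normexp and 42.3% with the authors' values. Of the quantile calls, 1421 were among the 3693.

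The H3K27me3 count of 6 moved to 1 with normexp, 0 with the authors' values, 40 with the median over probes, 37 with 3 adjacent probes, 2 without dim probes, 101 at 0.5 and 0 at 1.5. Regions with both marks (373 in control, 349 in PMA) were 46 and 33 with normexp, 109 and 118 with the authors' values, 5694 and 5426 with 3 adjacent probes, 3039 and 3039 at 0.5, 20 and 11 at 1.5, and 3288 and 3463 as the top 20% of each mark. With H3K4me3 from session A alone PMA had 208. Leaving out 1 array gave 354 to 381 and 307 to 373. The correlation of both differences was -0.21 with normexp and -0.16 with the authors' values, and 0.0324 in session A alone. Leaving out 1 array gave -0.16 (without control 1) to 0.0407, above 0 without control 2 (0.02), control 3 (0.00824) and PMA 1 (0.0407).

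In the immunoprecipitate channel alone the sign turned at chromosome 1 near 212737375 (-0.12), chromosome 21 near 30516579 (-0.00708) and the stretches on chromosome 19 from 50601082 (-0.0627) and chromosome 4 from 190994282 (0.0765), where the input carried the difference. H3K27me3 turned at chromosome 17 near 74483491 with the authors' values (0.00856) and near 67095704 with the median over probes (-0.50). Of 301 values of regions named under the session block, 26 lost their call: 14 in the immunoprecipitate channel alone, 6 with the median over probes and 6 with 3 adjacent probes. Several of these differences stayed about as large, such as 1.31 at chromosome 12 near 66220254 in the immunoprecipitate channel, 1.05 at chromosome 2 near 238418273 with the median and -1.09 at chromosome 3 near 167370789 with 3 adjacent probes. Others shrank, such as 0.24 at chromosome 14 near 95599340 with the median and 0.27 at chromosome 6 near 138188870 with 3 adjacent probes. The gene lists and their alternatives, set tests included, were not run, since no region could be matched to a gene. H3K27me3 had 1 array per side, so no array could be left out or paired. Dim probes limit the immunoprecipitate channel, with at least 79.7% of probes well above background on each array.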

Other observations

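The tests of neighbouring regions were chosen after the data were seen. H3K4me3 differences ran over neighbouring regions. With session as a block and quantile normalisation, 42 windows of 5 consecutive regions were on average at least 0.25 higher in PMA and 41 at least 0.25 lower. Shuffling regions within chromosomes gave 9.07 and 13.2 on average and at most 22 and 28 (permutation test, 1000 shuffles, one-sided p = 0.001, the smallest they can give); the windows overlap. Calls of 1 direction in a row of 3 or more regions occurred 5 times, against 1.03 by shuffling (p = 0.007, permutation test). The shuffles treat regions as exchangeable, so regions that share a start site or sequence could raise these counts, which was not tested.

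The differences given next are after quantile normalisation. The higher runs were chromosome 2 from 109203456 to 109238201 (0.34 in session A, 0.40 in session B), chromosome 4 from 88741262 to 88897301 (0.52 and 0.34), chromosome 10 from 91136512 to 91174824 (0.26 and 0.32) and chromosome 12 from 13248240 to 13350101 (0.41 and 0.42). The lower run was chromosome 14 from 105939811 to 105958085 (-0.15 and -0.34). Among windows, chromosome 1 from 149783428 to 149834025 was lower, at -0.34, and at -0.27 without its most changed region. The window on chromosome 12 from 65562050 to 66418806 rested on 1 region, with 0.34 over all 5 and 0.11 without the region near 66220254. The window on chromosome 9 from 21367575 to 21483612 was higher by 0.38 and had a mean input percentile of 1.08, among the dimmest. Those on chromosome 19 from 50601082 to 50617045 (0.36) and chromosome 4 from 190994282 to 191009262 (-0.35) held 0 called regions and had input percentiles of 99.3 and 98.9. The first was 0.88 in session A and 0.11 in session B, and the second -0.13 under median centring.

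Within session A the arrays of both marks parted over stretches of regions. H3K4me3 exceeded H3K27me3 most on chromosome 1 from 149802920 to 149860766, with mean values of 1.37 and 0.13 over 5 regions, and there H3K27me3 minus H3K4me3 was -1.49 in control and -1.001 in PMA. Chromosome 5 from 42992935 to 43122141 had 1.09 and -0.00439 in these marks, and chromosome 5 from 64063454 to 65019241 had 1.08 and 0.03. H3K27me3 exceeded H3K4me3 by less, at most by 0.39 over 5 regions, on chromosome 19 from 33555324 to 33718056 and chromosome 9 from 138592730 to 139012031. With 1 array per mark and condition in that session, none of this was tested. H3K4me3 arrays of different sessions also parted in a way that recurred between control and PMA (r = 0.887). These stretches therefore do not tell marks from preparations.

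Adjacent probes correlated at r = 0.19 in the H3K4me3 difference of each session, at 0.002 between controls 2 and 3, and at 0.04 in the H3K27me3 difference. PMA minus control in the input channel correlated at r = 0.24 between the H3K4me3 and H3K27me3 arrays of session A, at 0.14 between the H3K4me3 arrays of both sessions and at -0.07 between session B and the H3K27me3 arrays. In the immunoprecipitate channel it correlated at r = 0.22 between the H3K4me3 arrays of both sessions.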
